A study of Mus musculus with 64 samples.

How the data were processed

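RNA was sequenced from prefrontal cortex, hippocampus, hypothalamus and whole blood of male BALB/c mice, 64 libraries in all. Per the labels' protocols, tissue was taken 14 to 16 hours after the last stress, between ZT12.5 and ZT14.5, brain tissue was kept in RNAlater and trunk blood in blood RNA tubes, and directional libraries were made from 100 ng of total RNA after depletion of ribosomal RNA. The genome build was GRCm38.p4, per the submitters' processing notes. The aligner, the counting tool, its annotation, its use of strand and any filter are not given in the sources used here.

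The authors deposited 1 table per tissue, with Entrez numbers and symbols, whose file names call the values normalized read counts. The values as deposited were read as log2 levels that the authors had quantile normalized between libraries; both the log2 scale and that step were inferred from the values, since the labels name neither. They ran from 0.0350 to 19.8, and on base 2 the highest value of a table came to 341139, 374083, 600165 and 902771 in prefrontal cortex, hippocampus, hypothalamus and blood. The libraries of a table shared their distribution: at 89.0%, 89.4%, 88.7% and 72.4% of the ranks, all libraries were equal within 0.002, which is what quantile normalization between libraries gives. Genes with a single exon block in the GENCODE M21 annotation of GRCm38 had a median level of 6.26, 6.29, 6.26 and 4.96, against 4.31, 4.37, 4.38 and 3.31 for genes with introns, and made up 52, 52, 53 and 22 of the 100 highest genes, so levels of different genes are not comparable as transcript numbers. The symbols matched for this were 81.7% to 85.1% of a table. Whole reads could not be recovered and no count model was run. Depth is unknown and no counting interval is given. No symbol was given for 118, 115, 122 and 50 genes. The number of columns with no sample was 0, and no libraries of a table were identical (highest correlation within a group 0.988).

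Groups were treatment within tissue, as the labels give them. All choices of test, lists and named genes were made before the data were examined, unless said otherwise. Because the tables held log values, the planned branch for log values was used: limma 3.58.1 in R 4.3.3 was run per tissue on the values as deposited, with a trended prior variance, two-sided, after the 10% of genes with the lowest mean over all libraries of the table were left out (14127, 14015, 14539 and 7947 genes remained), and with Benjamini-Hochberg adjustment at 0.05. Differences are UCMS minus control on the log2 scale. The mean brain effect used the mean of the 3 regions in each of 16 animals and the 13517 genes tested in all 3. Differences between tissues used within-animal differences of levels, for 6 pairs of tissues. Correlations of effects across genes were set against 100 splits of the animals, relabelled alike in both tissues.

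Gene lists, 45 with 865 symbols (767 found in any table, older symbols matched through Entrez numbers), were tested in a tissue where at least 5 members were tested: 36 lists in prefrontal cortex, 35 in hippocampus, 36 in hypothalamus, 25 in blood and 33 for the mean of the brain regions. The main test was limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists of a tissue. Beside it stand camera with an estimated correlation, fry, which tests whether a list's genes move one way and does not compare them with other genes, and an exact permutation test of the list score (the mean over members of z-scores across libraries), the last chosen after seeing the data. Of these 3, none called a list in any tissue: the smallest adjusted p values were 0.434 with an estimated correlation, 0.220 with fry and 0.225 with the exact permutation test, all in blood. Members count as passing over the list alone when limma's p values are adjusted among them. Relations across animals used Pearson's r and Spearman's rho with two-sided permutation tests, exact up to 9 animals and otherwise with 100000 resamples.

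Named genes followed a rule: genes past the threshold, or, where fewer than 10 passed, the 10 named genes with the smallest unadjusted p, members of lists past camera with the smallest p, and fixed stress, apoptosis and hypothalamic peptide genes, from which the text gives a selection, as some genes are not reported here. Ttr was described after its values were seen. Coordinates come from GENCODE M21 on GRCm38.

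On simulated data with the real means and spreads and 200 changed genes, the gene test recovered 78%, 80%, 68%, 12% and 89% of genes changed by 0.5 on the log2 scale, and 91%, 96%, 95%, 61% and 99% of those changed by 1, in prefrontal cortex, hippocampus, hypothalamus, blood and the mean of the brain regions (14127, 14015, 14539, 7947 and 13517 genes). On simulated data for hippocampus (14015 genes), camera called 7 of 7 moved lists and 0 of 19 that were not moved. All members of the moved lists were raised alike, by more than any list median reported for hippocampus. The 7 of 7 therefore does not give the power at the sizes reported. These simulations drew genes independently, so they do not cover correlation between genes.

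Alternatives were pseudocounts of 0.1 and 2.5 ppm of the median column total on the linear scale, no filter and a mean of at least 5 ppm, quantile and median-of-ratios normalization, array weights, robust moderation, the exact Wilcoxon test, a replicate block, leaving out the animals whose number starts with BS, a composition covariate (myelin score in brain, erythroid score in blood), leaving out each library, the median level as score and combining the 2 within-table fits for differences between tissues. Added after seeing the data were fits without libraries whose Hbb-bs lay above 13, fits with the first 2 principal components of the residuals as covariates, leaving out each library in the list tests, and same-animal correlations without animals with such libraries. A value that passes no test has no called direction, so its change of sign was counted apart and not as a reversal. Figures were drawn with matplotlib 3.10.9.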

Results

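Total RNA was sequenced from 4 tissues of male BALB/c mice aged 28 weeks, some of which had gone through a 9-week schedule of Unpredictable Chronic Mild Stress (UCMS), a mouse model of depression, while the others stayed unstressed. Prefrontal cortex, hippocampus and hypothalamus were each sampled in 8 control and 8 UCMS animals, and whole blood in 7 control and 9 UCMS animals, giving 64 libraries from 17 animals. Each library of a group came from a separate animal, per the labels, and the animal numbers in the labels link the tissues of 1 animal. Replicate numbers do not link brain to blood: control replicate 7 is animal C7 in the brain regions and animal C8 in blood. The tables held 15697 genes for prefrontal cortex, 15573 for hippocampus, 16155 for hypothalamus and 8830 for blood, as normalized log2 levels, the base inferred from the values. Their sequencing depth is unknown, because the levels had been made equal in distribution between the libraries of a table. The spread between libraries, which also holds any counting error, set the precision. The median standard error of a gene's log2 difference was 0.0993 in prefrontal cortex, 0.0831 in hippocampus, 0.0823 in hypothalamus and 0.195 in blood.

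Hemoglobin RNA set some brain libraries apart from the rest. Hbb-bs (Entrez 100503605, GRCm38 chromosome 7, 103826534 to 103828096), which encodes adult beta-globin and shares reads with near-identical globin copies, had log2 levels of 14.03 to 14.57 in 9 brain libraries and of 4.02 to 9.63 in the other 39. The 9 libraries were control replicate 1 and UCMS replicate 6 in prefrontal cortex, control replicates 1 and 7 and UCMS replicate 6 in hippocampus, and control replicates 1 and 7 and UCMS replicates 6 and 8 in hypothalamus. Of these, 5 were control and 4 UCMS libraries, and they came from 4 animals, so they are not independent. In blood, Hbb-bs lay at 15.2 ± 0.34 (SD, n = 7) in controls and at 15.4 with no spread (n = 9) in UCMS, since quantile normalization gives a gene of the same rank the same value, so its test there has no meaning.

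**Figure D1:**
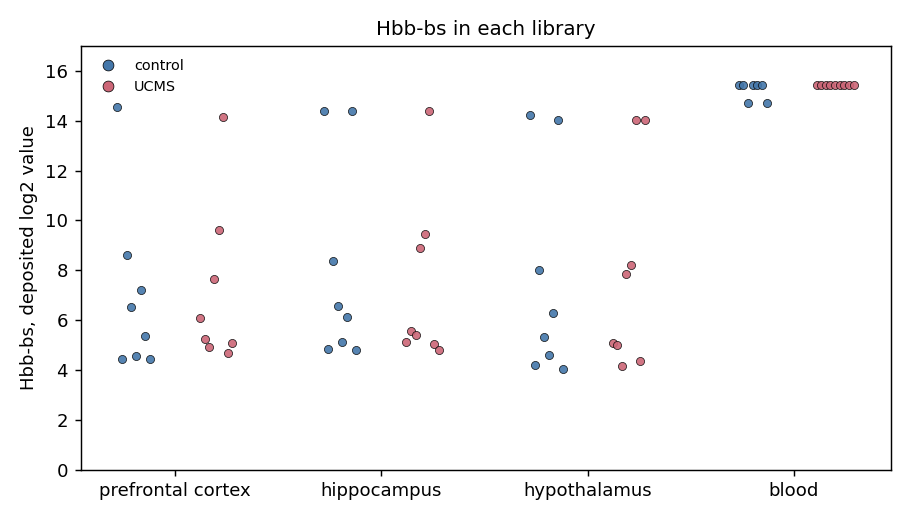
Deposited log2 level of Hbb-bs in each library, by tissue (x axis) and treatment (color), with no error bars. In the brain, 9 libraries lie at 14.03 to 14.57 and 39 at 4.02 to 9.63.

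The hippocampus comparison asked which transcripts chronic stress left higher or lower 14 to 16 hours after the last exposure. Genes known to respond to glucocorticoids, the adrenal stress hormones, were higher in UCMS animals in 25 of 28 measured members, with a median log2 difference of 0.11. The list score of 7 of the 8 UCMS animals lay above the control median. Cebpd (Entrez 12609, chromosome 16, 15887286 to 15891031), a C/EBP transcription factor, stood at a log2 level of 6.16 ± 0.22 (SD, n = 8) in controls and 6.47 ± 0.17 (n = 8) in UCMS, 24.3% higher (log2 standard error 0.0932). Plin4 (Entrez 57435, chromosome 17, 56100591 to 56109803), a lipid droplet coat protein, stood at 3.99 ± 0.30 and 4.42 ± 0.45. Fam107a, an actin-binding protein, stood at 7.79 ± 0.085 and 7.90 ± 0.085. Fkbp5, a co-chaperone of the glucocorticoid receptor, had near-equal means, 4.86 ± 0.10 and 4.86 ± 0.16, and was not tested against the list. Nr3c1, the receptor itself, stood at 5.78 ± 0.030 and 5.68 ± 0.29, where UCMS replicate 3 lay at 5.01 and the next lowest UCMS library at 5.61. The list passed limma's camera with a preset correlation (adjusted p = 2.48e-07), but had adjusted p = 0.636 with an estimated correlation. The two-sided exact permutation p of its score was 0.0222 (0.752 adjusted over 35 lists). No member passed over all genes, and 0 of 28 passed when adjusted over the list alone.

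The hippocampus held 4 further lists past camera with the preset correlation. Microglia genes were higher in 12 of 14 members (median 0.0714, adjusted p = 0.0187), among them C1qb, a complement component, at 4.73 ± 0.19 in controls and 4.99 ± 0.30 in UCMS (SD, n = 8 each). Genes typical of hippocampal neurons were higher in 12 of 14 members (median 0.0966, adjusted p = 0.0134), with Lct at 3.93 ± 0.20 and 4.19 ± 0.24. Nuclear genes of oxidative phosphorylation, the respiratory chain and ATP synthase, were lower in 31 of 37 members (median -0.0429, adjusted p = 0.00096), with Cox6c, a cytochrome oxidase subunit, at 7.44 ± 0.075 and 7.32 ± 0.090. Meningeal and fibroblast genes were lower in 8 of 9 members (median -0.10, adjusted p = 0.0458), with Dcn, a matrix proteoglycan, at 5.20 ± 0.22 and 4.85 ± 0.40. With an estimated correlation the adjusted p values were 0.636 for microglia genes and 0.753 for each of the other three lists, and 0 members of the 4 lists passed over all genes or adjusted over the list alone. Without the hemoglobin-rich libraries the microglia, hippocampal neuron and meningeal lists no longer passed (camera adjusted p = 0.172, 0.0519 and 0.0873).

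Over all 14015 genes tested in hippocampus, limma found 0 at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 414, of which 234 were higher and 180 lower in UCMS, where 5% of the genes would be 701. Without UCMS replicate 6 there were 688. Sirt4 (Entrez 75387, chromosome 5, 115478010 to 115484725), a mitochondrial sirtuin, had the smallest unadjusted p (adjusted p = 0.990, shared by many genes), with 3.81 ± 0.13 (SD, n = 8) in controls and 4.14 ± 0.11 (n = 8) in UCMS. The next 9 by unadjusted p were Cep41, Naif1, Lsm1, Zfp791, Armcx1, Klc3, Dync1h1, Ifit3b and Thumpd1, with log2 differences from -0.39 (Cep41) to 0.38 (Klc3), and none passed.

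In hypothalamus, the centre of the hormonal stress axis, glucocorticoid-responsive genes were higher in UCMS in 23 of 28 members, with a median log2 difference of 0.11. Of the UCMS animals, 6 of 8 scored above the control median. Fam107a (Entrez 268709, chromosome 14, 8296274 to 8318023) stood at 7.17 ± 0.15 (SD, n = 8) in controls and 7.34 ± 0.12 (n = 8) in UCMS. Sult1a1, a sulfotransferase, stood at 3.22 ± 0.42 and 3.68 ± 0.47, and Sgk1, a glucocorticoid-induced kinase, at 4.74 ± 0.44 and 5.10 ± 0.47. The list passed camera with the preset correlation (adjusted p = 1.69e-05) and had adjusted p = 0.694 with an estimated correlation and a two-sided exact permutation p of 0.0514. Cytosolic ribosomal protein genes, many of which have near-identical pseudogene copies, were lower in 29 of 32 members (median -0.0466, camera adjusted p = 1.79e-06), with Rps14 at 7.22 ± 0.10 and 7.12 ± 0.066. Heat shock and unfolded protein genes were higher in 22 of 26 members (median 0.0509, adjusted p = 0.000553, but 0.0856 without the hemoglobin-rich libraries), with the chaperone Hsph1 (Entrez 15505, chromosome 5, 149614287 to 149636376) at 6.61 ± 0.068 and 6.73 ± 0.077. Meningeal and fibroblast genes were higher in 10 of 10 members (median 0.38, adjusted p = 0.00418, but 0.465 without UCMS replicate 2), with Mgp, matrix Gla protein, at 3.84 ± 0.60 and 4.60 ± 1.05. Interferon-stimulated genes were higher in 9 of 10 members (median 0.12, adjusted p = 0.0322), but that list's camera adjusted p was 0.744 without UCMS replicate 2, 0.106 with the myelin score as a covariate and 0.0648 without the animals whose number starts with BS. Each of these 4 lists had adjusted p = 0.957 with an estimated correlation, and 0 members of the 5 lists passed over all genes or adjusted over the list alone.

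The peptide genes of hypothalamic neurons varied widely between animals. Avp (Entrez 11998, chromosome 2, 130580620 to 130582554), which encodes vasopressin, stood at a log2 level of 9.09 ± 0.78 (SD, n = 8) in controls and 7.98 ± 2.16 (n = 8) in UCMS. Oxt (Entrez 18429, chromosome 2, 130576173 to 130577054), which encodes oxytocin, stood at 7.45 ± 1.02 and 6.45 ± 1.93. The Avp difference of -1.11 had a standard error of 0.75, and neither gene passed. Without UCMS replicate 7 the difference was -0.45 for Avp and -0.40 for Oxt. Crh, corticotropin-releasing hormone, stood at 4.02 ± 0.69 and 3.86 ± 0.63. Hcrt, the wake-promoting orexin precursor, stood at 8.27 ± 0.33 and 8.41 ± 0.32, and Pmch, the precursor of the REM sleep-linked melanin-concentrating hormone, at 9.40 ± 0.39 and 9.53 ± 0.37. Differences for Pomc, Agrp, Npy, Gal and Trh lay between -0.35 (Trh) and 0.43 (Agrp). Without control replicate 5 the difference was -0.52 for Pomc and 0.0960 for Agrp. As lists, stress axis and corticosteroid receptor genes (17 members, camera adjusted p = 0.365), sleep-wake neuropeptide and adenosine genes (20 members, 0.389) and hypothalamic neuron genes (21 members, 0.838) did not pass. Bdnf (Entrez 12064, chromosome 2, 109674700 to 109727007), a neurotrophin, stood at 4.71 ± 0.36 and 5.06 ± 0.22, a log2 difference of 0.35 (standard error 0.14) that did not pass over all genes.

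Over the 14539 genes tested in hypothalamus, limma found 0 at an adjusted p under 0.05 and 308 at an unadjusted p under 0.05 (138 higher, 170 lower), where 5% would be 727. Smco4 (Entrez 170748, chromosome 9, 15493432 to 15545260), a single-pass membrane protein, came first with 4.71 ± 0.21 (SD, n = 8) in controls and 4.34 ± 0.14 (n = 8) in UCMS, and its adjusted p of 0.99999 was shared by many genes. Among the next by unadjusted p, Mis12, Zdhhc4, Vps37c, Dhrs7b, Hyal1, Tbc1d10a and Atp6v0a4 had log2 differences from -0.23 (Zdhhc4) to 0.45 (Atp6v0a4) and did not pass.

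In prefrontal cortex no gene list passed camera. The glucocorticoid-responsive list came closest, with 23 of 27 members higher in UCMS, a median log2 difference of 0.0913 and 6 of 8 UCMS animals above the control median. Its camera adjusted p was 0.0962, with adjusted p = 0.985 with an estimated correlation and a two-sided exact permutation p of 0.157 for the score. Its members Per1, a clock gene with glucocorticoid response elements, and Sgk1 stood at 5.33 ± 0.17 and 4.89 ± 0.34 (SD, n = 8) in controls and at 5.45 ± 0.20 and 5.07 ± 0.38 (n = 8) in UCMS. The list passed without UCMS replicate 8, the only animal there whose number starts with BS (camera adjusted p = 0.00306). It also passed with the myelin score as a covariate (0.01001) and without the hemoglobin-rich libraries (0.0222). It did not pass in 11 of 16 fits with 1 library left out (highest camera adjusted p = 0.376, without UCMS replicate 4). Limma found 0 of 14127 genes at an adjusted p under 0.05 and 308 at an unadjusted p under 0.05 (138 higher, 170 lower), where 5% would be 706. The smallest adjusted p, 0.987, was shared by many genes, and the smallest unadjusted p belonged to an unnamed gene model, 2310047K21Rik. The first 10 named genes by unadjusted p were Cstf1, Galns, Nudcd2, Trim27, Ppp1r3b, Ocln, Phkg1, Snhg6, Nop16 and Mmgt1, with log2 differences from -0.81 (Ppp1r3b, a glycogen-targeting phosphatase subunit) to 0.47 (Galns, a lysosomal sulfatase), and none passed.

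**Figure D2:**
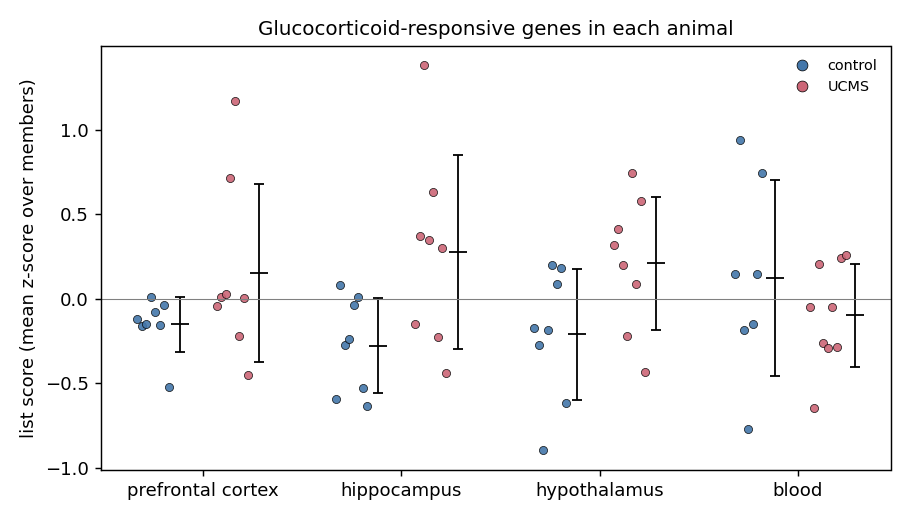
Glucocorticoid-responsive list score (mean z-score over members, no unit) of each animal, by tissue (x axis) and treatment (color), with the group mean and SD as black bars. In hippocampus the mean was -0.28 ± 0.28 in 8 control and 0.28 ± 0.57 in 8 UCMS animals.

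Apoptosis and the stress axis, which the title of the series names, were examined with lists fixed for them. Pro-apoptotic genes (30 members in prefrontal cortex and hippocampus, 31 in hypothalamus, 22 in blood) had median log2 differences of 0.0245, 0.00181, -0.0428 and -0.0678. Their camera adjusted p values were 0.612, 0.696, 0.455 and 0.838, and in hippocampus the test pointed down while the median lay above 0. Anti-apoptotic genes (17, 16, 17 and 17 members) had medians of -0.0654, -0.00269, 0.0249 and 0.0404, with adjusted p values of 0.387, 0.696, 0.838 and 0.318. Bcl2, which blocks apoptosis, stood at 7.37 ± 0.098 (SD, n = 8) in controls and 7.19 ± 0.30 (n = 8) in UCMS in prefrontal cortex, where UCMS replicate 5 lay at 6.48 and the next lowest UCMS library at 7.13. In hippocampus Bcl2 stood at 6.78 ± 0.11 and 6.69 ± 0.22. Bax, its pro-apoptotic counterpart, stood at 4.59 ± 0.15 and 4.63 ± 0.16 in hippocampus. Neither gene passed over all genes, and 0 members of either list passed adjusted over the list alone in any of the 4 tissues. Stress axis and corticosteroid receptor genes did not pass in prefrontal cortex (11 members, 0.677) or hippocampus (9 members, 0.886), nor did immediate early genes (camera adjusted p = 0.683 in prefrontal cortex, 0.310 in hippocampus and 0.905 in hypothalamus).

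Averaging the 3 brain regions of each animal lowered the spread, with a median standard error of 0.0538. Glucocorticoid-responsive genes were higher in UCMS in 26 of 27 members, with a median log2 difference of 0.10, and 7 of 8 UCMS animals scored above the control median. The list had a camera adjusted p of 1.11e-06, but adjusted p = 0.496 with an estimated correlation. The two-sided exact permutation p of its score was 0.0179 (0.590 adjusted over 33 lists). Plin4 stood at 4.10 ± 0.41 (SD, n = 8) in controls and 4.48 ± 0.42 (n = 8) in UCMS, and Bcl6, a transcriptional repressor, at 4.37 ± 0.16 and 4.52 ± 0.11. Circadian clock genes were higher in 16 of 22 members (median 0.0353, camera adjusted p = 0.0183, but 0.120 without the BS animals), among them Ciart, a transcriptional repressor of the clock, at 3.91 ± 0.11 and 4.09 ± 0.12, and Per2, a core clock repressor, at 4.04 ± 0.11 and 4.16 ± 0.055. Cytosolic ribosomal protein genes were lower in 26 of 32 members (median -0.0263, camera adjusted p = 0.0183, but 0.491 without UCMS replicate 4). These last lists both had adjusted p = 0.933 with an estimated correlation, and 0 members of the 3 lists passed over all genes or adjusted over the list alone. Limma found 0 of 13517 genes at an adjusted p under 0.05 and 489 at an unadjusted p under 0.05 (201 higher, 288 lower). The unadjusted count was 926 without the animals with hemoglobin-rich libraries, and 304 to 892 with 1 animal left out (304 without UCMS replicate 3, 313 without UCMS replicate 5, 892 without UCMS replicate 6). The first 10 named genes were Zfp964, Cep57l1, Ccpg1os, Ccl28, Plxna2, Foxj2, Snhg6, Ifit3b, Ina and Cmklr1, with log2 differences from -0.41 (Ccl28, a chemokine) to 0.23 (Cmklr1, a chemerin receptor).

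Blood had the widest differences between the treatments, with a median absolute log2 difference of 0.183, but also the widest standard errors (median 0.195). Platelet and megakaryocyte genes were lower in UCMS in 17 of 17 members, with a median log2 difference of -0.43, and 1 of 9 UCMS animals scored above the control median. Pf4 (Entrez 56744, chromosome 5, 90772435 to 90773383), platelet factor 4, stood at a log2 level of 9.63 ± 0.26 (SD, n = 7) in controls and 9.13 ± 0.52 (n = 9) in UCMS. Tubb1, the platelet beta-tubulin, stood at 7.38 ± 0.21 and 6.88 ± 0.37. Of the 17, 0 passed over all genes and 8 when adjusted over the list alone (among them Gp1ba, Tubb1, Nrgn, Gp5, Pf4, Gp1bb and Alox12). The list passed camera with the preset correlation (adjusted p = 2.39e-10), but had adjusted p = 0.434 with an estimated correlation and a two-sided exact permutation p of 0.0144 (0.225 adjusted over 25 lists).

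Cell cycle genes were higher in the blood of UCMS animals in 14 of 14 members, with a median log2 difference of 0.44, and 8 of 9 UCMS animals scored above the control median. Mki67 (Entrez 17345, chromosome 7, 135689784 to 135716361), a proliferation marker, stood at 4.15 ± 0.42 (SD, n = 7) in controls and 4.76 ± 0.41 (n = 9) in UCMS. Tpx2, a spindle assembly factor, stood at 3.57 ± 0.46 and 4.25 ± 0.39. Erythroid genes were higher in 18 of 20 members, with a median of 0.33, and in 8 of 9 UCMS animals by the same measure. Tfrc (Entrez 22042, chromosome 16, 32608920 to 32632794), the transferrin receptor of red cell precursors, stood at 5.19 ± 0.75 and 5.95 ± 0.32. Rhag, a red cell membrane glycoprotein, stood at 4.15 ± 0.38 and 4.71 ± 0.32. Oxidative phosphorylation genes were higher in 24 of 31 members, with a median of 0.11, and Cox6c stood at 5.24 ± 0.42 and 5.75 ± 0.36. Camera with the preset correlation gave adjusted p values of 8.03e-07 for cell cycle, 7.89e-06 for erythroid and 0.0185 for oxidative phosphorylation genes, and with an estimated correlation adjusted p = 0.434, 0.434 and 0.565. The two-sided exact permutation p values of the scores were 0.0180, 0.0477 and 0.0690, and 0 members passed over all genes, against 3, 0 and 0 adjusted over the list alone. With the erythroid score as a covariate the oxidative phosphorylation list no longer passed (camera adjusted p = 0.221).

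**Figure D3:**
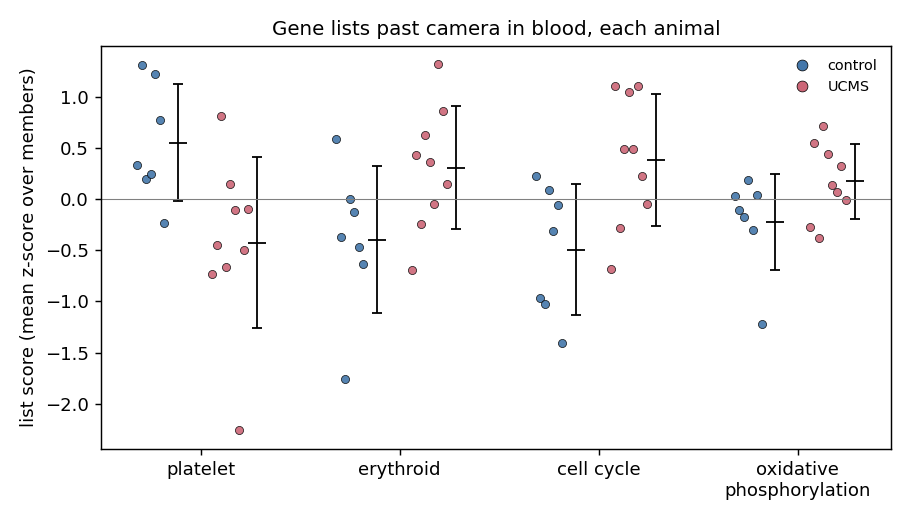
Scores (mean z-score over members, no unit) of the 4 gene lists past camera in blood, for each of 7 control and 9 UCMS animals, with the group mean and SD as black bars. The platelet list was lower in 17 of 17 members and the cell cycle list higher in 14 of 14.

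Over the 7947 genes tested in blood, limma found 0 at an adjusted p under 0.05 and 859 at an unadjusted p under 0.05 (10.8%), where 5% would be 397. With the erythroid score as a covariate the unadjusted count was 308, and with a mean of at least 5 ppm of the median column total it was 490, among fewer genes. Of the 859, 515 were higher and 344 lower in UCMS. Wdr76 (Entrez 241627, chromosome 2, 121506723 to 121544860), a WD repeat protein, stood at 1.96 ± 0.46 (SD, n = 7) in controls and 3.14 ± 0.38 (n = 9) in UCMS, a log2 difference of 1.18 with a standard error of 0.22 and the smallest adjusted p in blood (0.240). With a pseudocount of 2.5 ppm its difference was 0.56. It passed when UCMS replicate 2 was left out (log2 difference 1.28, limma adjusted p = 0.0442). The next 9 were Mtm1, Palb2, Tmem80, Emc8, Fads3, Rrp7a, Ugt8a, E2f7 and Gpld1, from -1.02 (Mtm1, a lipid phosphatase) to 1.25 (E2f7, a cell cycle repressor), and none passed. Glucocorticoid-responsive genes in blood did not pass (16 members, camera adjusted p = 0.300), and Nr3c1 stood at 3.99 ± 0.19 and 3.75 ± 0.21.

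In each of the 4 tissues, array weights, robust variance moderation and the exact Wilcoxon test also called 0 genes. Their counts at an unadjusted p under 0.05 were 462, 307 and 383 in prefrontal cortex, 927, 404 and 562 in hippocampus, 389, 309 and 339 in hypothalamus, and 761, 863 and 682 in blood, and array weights gave 0 and 543 for the mean of the brain regions. With so few animals, the exact Wilcoxon test can pass adjustment only if many genes reach its smallest possible p, so its 0 says little. Camera's calls with the preset correlation were as numerous in many other splits of the same animals: the median of the other splits drawn was 4 lists in hippocampus, 7 in hypothalamus, 4 in blood and 7 for the mean of the brain regions, against 5, 5, 4 and 3 for the treatment.

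The effect of UCMS was compared between tissues through the differences within each animal. Wdr76 differed between hypothalamus and blood, with a log2 difference of -0.29 (standard error 0.13) in hypothalamus and 1.18 in blood (difference -1.53, standard error 0.23, limma adjusted p = 0.0140 over 7130 genes, 7 control and 8 UCMS animals). With a pseudocount of 2.5 ppm that difference was -0.80 (adjusted p = 0.0337). In the other pairs of tissues limma called 0 genes, with 221 genes at an unadjusted p under 0.05 between prefrontal cortex and hippocampus, 334 between prefrontal cortex and hypothalamus, 310 between hippocampus and hypothalamus, 614 between prefrontal cortex and blood, and 696 between hippocampus and blood. With array weights these pairs also had 0 genes, but combining the 2 within-table fits called Mtm1, Wdr76 and Snhg8 between prefrontal cortex and blood and Wdr76 between hippocampus and blood, so the Wdr76 difference is not shown to be particular to hypothalamus. In 52 comparisons of list scores between tissues none passed (lowest adjusted exact permutation p = 0.277), so no list was shown to differ between tissues.

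Across genes, which are not independent replicates, the log2 differences of prefrontal cortex and hippocampus had a Spearman correlation of 0.38 (Pearson 0.41), and 14 of 100 splits of the animals gave one as high (adjusted p = 0.840 over 6 pairs, permutation of animals). The other pairs had Spearman values of 0.0388 for prefrontal cortex with hypothalamus, 0.10 for hippocampus with hypothalamus, and -0.13, -0.12 and -0.0699 for prefrontal cortex, hippocampus and hypothalamus with blood. The adjusted permutation p, one-sided for a higher correlation, was 0.910 each and so does not test the negative values. With blood it used the 15 animals with both tissues, where the Spearman values were -0.160, -0.157 and -0.0868.

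The tissues of 1 animal were also compared over all genes, as the mean correlation of deviations from the group mean with globins left out. It was 0.307 between prefrontal cortex and hippocampus (one-sided permutation p = 7e-05), and 0.254 and 0.328 for hypothalamus with prefrontal cortex and with hippocampus (permutation p = 1e-05, the smallest the resamples can give). Between regions of different animals it was -0.0171, -0.0170 and -0.0205. With blood it was 0.00196, 0.0236 and 0.00265 for the 3 regions (permutation p = 0.467, 0.0970 and 0.426). Hemoglobin-rich libraries of 1 animal also share other blood RNA. Without the 4 animals that had any, a setting chosen after seeing the data, the values between the brain regions were 0.276, 0.254 and 0.298 in the same order (permutation p = 0.00494, 6e-05 and 1e-05, 12 animals).

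Across animals, the glucocorticoid-responsive scores of the brain regions were compared with one another and with blood, as a family of 6 relations. Pearson's r over 16 animals was 0.541 between prefrontal cortex and hippocampus (Spearman's rho 0.656), 0.513 between prefrontal cortex and hypothalamus (rho 0.591) and 0.521 between hippocampus and hypothalamus (rho 0.594). The two-sided permutation p values were 0.0423, 0.0423 and 0.0370 for r and 0.00735, 0.0173 and 0.0166 for rho. The adjusted permutation p was 0.0635 for each r, which did not pass, and 0.0220, 0.0260 and 0.0260 for rho, which passed. These scores were not centred within treatment, so a UCMS shift shared by the regions can add to the pooled values. The relations were not repeated without the animals with hemoglobin-rich libraries, so blood RNA shared by regions can add to them too. With the median level as score none passed (lowest adjusted permutation p 0.171 for r and 0.180 for rho). On the mean score, r was 0.540, 0.649 and 0.498 without the 2 animals farthest from the median. With blood, over 15 animals, r was -0.417 for prefrontal cortex (permutation p = 0.123, adjusted 0.148, rho -0.582 with p = 0.0250, adjusted 0.0300), -0.263 for hippocampus (permutation p = 0.339, adjusted 0.339, rho -0.457 with p = 0.0886, adjusted 0.0886) and -0.634 for hypothalamus (permutation p = 0.0102, adjusted 0.0612, rho -0.689 with p = 0.00517, adjusted 0.0220). Without the 2 farthest animals these became -0.545, -0.505 and -0.530. With the median log2 level of the members as score, r was 0.356, 0.486 and 0.537 between the brain regions in the same order, and -0.221, -0.0915 and -0.264 with blood. Within treatments, r between prefrontal cortex and hippocampus was 0.350 in 8 control and 0.446 in 8 UCMS animals (two-sided exact p = 0.470 and 0.267), with rho -0.0238 and 0.881 (exact p = 0.977 and 0.00724), and r was -0.526 and 0.705 without the 2 farthest animals of a treatment. Between prefrontal cortex and hypothalamus r was 0.520 and 0.433 (exact p = 0.191 and 0.283). The value between hippocampus and hypothalamus was 0.254 in 8 control and 0.412 in 8 UCMS animals (two-sided exact p = 0.534 and 0.315), and r between hypothalamus and blood was -0.738 in 7 control and -0.550 in 8 UCMS animals (exact p = 0.0581 and 0.157). With blood, r was -0.571 and -0.428 for prefrontal cortex (exact p = 0.198 and 0.288) and -0.231 and -0.0856 for hippocampus (exact p = 0.594 and 0.843).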

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

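All tests of the hemoglobin-rich libraries, the test of the glucocorticoid list without those libraries, the tests with each library left out of a list test and the test of platelets alone were chosen after the data were seen, and the others before. Of 403 groups of samples examined, 36 held a sample far from the others (14 control, 22 UCMS groups). Chance alone does this in about 1 in 20 groups. The values in this part are the gap from that sample to its nearest neighbor over the range of the group.

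In prefrontal cortex, UCMS replicate 5 was lowest for Nr3c1 (0.659), Bcl2 (0.693) and Mmgt1 (0.640), control replicate 2 lowest for Bdnf (0.530) and control replicate 4 highest for Nudcd2 (0.694). In hippocampus, UCMS replicate 3 was lowest for Nr3c1 (0.683) and Ndufc1 (0.682) and highest for Per1 (0.588), Tmem119 (0.671) and Csf1r (0.685). Control replicate 5 was lowest for Lsm1 (0.555) and control replicate 8 for the oxidative phosphorylation score (0.560).

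In hypothalamus, control replicate 5 was lowest for Bdnf (0.553), Pomc (0.693), Agrp (0.590) and Gal (0.618). Its Pomc level was 1.48 and the next 4.62. UCMS replicate 2 was highest for Fos (0.593), Oasl2 (0.596), Ddx58 (0.722), Hyal1 (0.533) and the interferon score (0.727). UCMS replicate 7 was lowest for Oxt (0.559), at 2.25 with the next at 5.63. The lowest Pmch was control replicate 1 (0.539) and the lowest Ifih1 control replicate 6 (0.547).

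In blood, UCMS replicate 7 was lowest for Tsc22d3 (0.565), Tubb1 (0.495), Nrgn (0.626), Pf4 (0.652) and the platelet score (0.498). Control replicate 7 (animal C8) was lowest for Cox7b (0.635) and the oxidative phosphorylation score (0.651), and control replicate 3 (animal C4) for Atp5b (0.778). UCMS replicate 2 was lowest for Wdr76 (0.518), and control replicate 2 highest for Rrp7a (0.718). For the mean of the brain regions, UCMS replicate 6 was lowest for Plxna2 (0.553).

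The UCMS effect on Wdr76 differed between hypothalamus and blood (limma adjusted p = 0.0140). Of 100 splits of the animals, 4, the real one included, gave as many genes for this difference (1 real, 1 in the highest other). Chance is excluded at 0.05 only for this pair of tissues taken alone, and it is not excluded over the 6 pairs, among which this one was singled out by its call.

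The first pattern is the hemoglobin RNA of 9 brain libraries. Chronic stress as its cause is argued against by the 5 such libraries from control animals, which are 2 animals. Blood left in the whole brain of an animal is argued against for control replicate 7 and UCMS replicate 8. Their regions went as low as 5.37 and 4.79 beside high ones. Control replicate 1 and UCMS replicate 6 were high in all 3 regions (lowest 14.2 and 14.0), so for them it stays open. Blood in the dissected tissue stays open. Against what the hemoglobin share needs, 301 values of other genes abundant in blood lay on median 0.509 below (quartiles -0.34 and 1.02). Their median shortfall was 0.988 in prefrontal cortex, 0.901 in hippocampus and 0.0460 in hypothalamus. For 60 values of white cell and platelet genes it was -0.194 (-0.90 and 0.46), slightly above that need. Against the other brain libraries, the median rise was 2.60 for the 301 values (2.84 needed) and 3.01 for the 60 (2.54 needed). Other blood RNA was thus higher in these libraries, among the genes that could be used. How far it matches the hemoglobin share, these values cannot decide. The share sets brain Hbb-bs against blood Hbb-bs, from tables normalized apart, where levels follow ranks. Only genes present in a brain table could be used, and some were low in the other libraries (Gp6 in hypothalamus 0.336, against 3.97 in these). Genes that did not rise may therefore be missing.

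The second pattern is the glucocorticoid-responsive list in hippocampus. Its camera adjusted p was 4.07e-05 without the hemoglobin-rich libraries, 8.55e-07 with the oligodendrocyte score as covariate and at most 0.000152 with 1 library left out (UCMS replicate 3). The list's median log2 difference was 0.109 without those libraries and 0.111 with that covariate, so neither removed the shift. No single library carried the call. Camera with the preset correlation gave as many lists of any kind in 47 of 100 splits of the animals, the real one included. How often a split gave this list so small a p was not counted. The splits also do not test blood, the share of oligodendrocytes or a single library. Camera's p values rest on the preset correlation, so they alone cannot exclude these as a cause. The list had adjusted p = 0.636 with an estimated correlation, so correlation among its members stays open, as does an effect of chronic stress.

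The third pattern is the lower platelet and higher erythroid and cell cycle lists in blood. With 1 library left out, the platelet camera adjusted p was at most 7.16e-08 (without control replicate 5), so no single library carried camera's call. Camera with the preset correlation gave as many lists of any kind in 65 of 100 splits, the real one included, which does not test a single library. Its p values rest on the preset correlation, so they alone cannot exclude a single library. The platelet score of UCMS replicate 7 was -2.26, with the next lowest at -0.731, and the exact permutation test was not repeated without it. A lower share of platelets alone would raise the other blood cell types alike. T cell, B cell, monocyte and neutrophil genes had a median of -0.17 over 64 members, against 0.33 for 20 erythroid genes. The permutation p over genes was 1e-05, the smallest possible. Genes are not independent, so this p measures no spread between animals. The erythroid score had an adjusted exact permutation p of 0.246 and no white cell list passed camera, so platelets alone stay open. Young red cells that carry cell cycle RNA may link the 2 higher lists: their scores, centred within treatment, had r = 0.709 over 16 animals (permutation p = 0.00264, adjusted 0.00792 over 3 relations, rho 0.776, and 0.622 without the 2 farthest animals). Within treatments r was 0.686 (exact p = 0.0677) and 0.735 (exact p = 0.0234), and with the erythroid score as covariate the cell cycle list had a camera adjusted p of 0.0109 (8.03e-07 without it, and 0.434 with an estimated correlation), which leaves open how much of it the link covers.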

How the results depend on the processing

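The tests without hemoglobin-rich libraries, with 2 residual components, with the exact permutation of list scores and with each library left out of list tests were chosen after the data were seen. Gene counts at an adjusted p under 0.05 stayed 0 in prefrontal cortex, hippocampus, hypothalamus and the mean of the brain regions under every alternative run. In blood the count was 152 with 2 residual components (116 higher, 36 lower) and 0 to 1 with 1 library left out, where the 1 was Wdr76 without UCMS replicate 2 (adjusted p = 0.0442). The components came from values centred within treatment, so by construction they change the residual spread and not the log2 differences. Why Wdr76 passed with that library left out was not tested. The lists past camera numbered 5 in hippocampus, 5 in hypothalamus, 4 in blood and 3 for the mean of the brain regions, but 0 in each with an estimated correlation, with fry and with the exact permutation of list scores. In hippocampus 2 passed without hemoglobin-rich libraries. In prefrontal cortex, against 0, 1 passed without the BS animals (in the brain regions only UCMS replicate 8), 1 with the composition covariate and 2 without hemoglobin-rich libraries. With 1 library left out, list counts ran from 0 to 3 in prefrontal cortex (2 without control replicate 1, control replicate 2 or UCMS replicate 6, 3 without control replicate 7, 1 without UCMS replicate 8), 3 to 9 in hippocampus (3 without control replicate 8, 9 without UCMS replicate 3), 2 to 7 in hypothalamus (2 without control replicate 2, 3 without control replicate 3), 3 to 9 in blood (9 without UCMS replicate 1, 7 without control replicate 5 or 6) and 1 to 6 for the mean of the brain regions (1 without control replicate 2 or UCMS replicate 1, 5 without control replicate 1, 6 without UCMS replicate 5). By list, the highest camera adjusted p with 1 library left out was 0.0918 for microglia (UCMS replicate 4), 0.160 for hippocampal neuron (UCMS replicate 4) and 0.266 for meningeal genes (UCMS replicate 7; 0.0616 without the BS animals) in hippocampus, 0.465 for meningeal (UCMS replicate 2) and 0.247 for heat shock genes (control replicate 2) in hypothalamus, 0.244 for oxidative phosphorylation in blood (control replicate 7), and 0.197 for clock (UCMS replicate 1) and 0.491 for ribosomal genes (UCMS replicate 4) in the mean of the brain regions. The erythroid list in blood turned to the other direction (adjusted p = 0.956) with the composition covariate, which is that list's own score. Differences between tissues, combining the 2 within-table fits, gave 3 genes for prefrontal cortex and blood and 1 for hippocampus and blood, and 0 for hypothalamus and blood with a mean of at least 5 ppm (parts of the median column total), a filter that removes Wdr76. For Wdr76 the adjusted p of that difference ran from 0.0001 to 0.0479 and the difference from -1.53 to -0.80 where it was tested, and its log2 difference in blood was 0.56 with a pseudocount of 2.5 ppm. Counts at an unadjusted p under 0.05 moved more than gene calls: with 2 residual components they were 742, 671, 630 and 1522 in prefrontal cortex, hippocampus, hypothalamus and blood, and with the composition covariate 494 in hypothalamus and 308 in blood. With array weights they were 927 in hippocampus, 534 for prefrontal cortex against hippocampus and 491 for hippocampus against hypothalamus. With a mean of at least 5 ppm, which tests fewer genes, they were 347, 369 and 297 for the differences with blood. With the replicate number as a block, gene counts stayed 0 and lists numbered 0, 6, 6, 6 and 4, but the labels do not say that those numbers pair the samples. The mean correlation of same-numbered samples was 0.219 in prefrontal cortex (6 of 8 pairs over 0.1) and 0.0190, -0.00787 and 0.0147 in hippocampus, hypothalamus and blood. Of 185 named gene values, none was called to begin with, 76 of 5295 alternatives changed a sign, and 15 passed the threshold, 14 of them in blood with 2 residual components. Quantile normalization moved values hardly at all (414 to 413 genes at an unadjusted p under 0.05 in hippocampus), because the tables already were so normalized, and says nothing about stability. The count test was not run, since whole reads could not be recovered, and unknown depth leaves open how far counting error limits low genes.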

Other observations

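In this part, the exact permutation tests of list scores and the setting with 2 residual components were chosen after the data were seen, and the other tests before. Genes of the choroid plexus, the tissue that secretes cerebrospinal fluid, were lower in UCMS for the mean of the brain regions in 5 of 5 members, with a median log2 difference of -0.25. The list did not pass (camera adjusted p = 0.0730, two-sided exact permutation p = 0.177). Ttr, the thyroid hormone carrier of that tissue, had levels of 6.66 ± 2.40 (SD, n = 8) in controls and 5.01 ± 1.46 (n = 8) in UCMS prefrontal cortex. Control replicate 2 had Ttr at 11.8 there, and the other controls lay at 3.59 to 7.44. In hippocampus Ttr was highest in UCMS replicate 3 (12.8), then in control replicates 5 (12.2) and 8 (11.6). UCMS replicate 2 (10.5) and control replicate 6 (10.1) followed. No fit used the choroid plexus score as a covariate. The list had camera adjusted p values of 0.243 in prefrontal cortex, 0.310 in hippocampus and 0.905 in hypothalamus, and the oligodendrocyte and myelin list 0.414, 0.383 and 0.641.

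In blood, white cell genes lay lower in UCMS without passing. T cell genes were lower in 19 of 21 members (median -0.16, camera adjusted p = 0.0661), monocyte and macrophage genes had a median of -0.29 (adjusted p = 0.0818), neutrophil genes were lower in 13 of 14 (median -0.15, adjusted p = 0.106) and B cell genes in 14 of 17 (adjusted p = 0.222). Nuclear-retained and histone RNA genes had a median of -0.20 (camera adjusted p = 0.0692, exact permutation p = 0.0374), with 3 of 9 members passing when adjusted over the list alone and 0 over all genes.

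The counts of splits include the real one. Of 100 splits of the animals, 82 gave as many genes at an unadjusted p under 0.05 as the real one in prefrontal cortex (308 real, 2051 in the highest other), 68 in hippocampus (414 and 1747), 84 in hypothalamus (308 and 2967), 7 in blood (859 and 1479) and 52 for the mean of the brain regions (489 and 2109). As many lists past camera came in 47 splits in hippocampus (5 real, 18 in the highest other), 76 in hypothalamus (5 and 18), 65 in blood (4 and 14) and 91 for the mean of the brain regions (3 and 16). With 2 residual components in blood, 5 splits gave as many genes (152 real, 915 in the highest other). Chance cannot be excluded for any of these counts. Splits that called several times the real count point to a structure of the samples, such as genes that vary together, which was not identified.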
